A study of Mus musculus with 2 samples.

How the data were processed

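Gene expression was measured with short-oligonucleotide arrays in G1E cells, a mouse erythroid progenitor line that lacks GATA-1. The cells expressed ER-GATA-1(V205G), a fusion of an estrogen receptor ligand-binding domain to a GATA-1 mutant that binds its cofactor FOG-1 poorly. Per the labels, the extracted molecule was total RNA and the label was biotin. There was 1 array for cells before treatment and 1 array for cells given 1 µM estradiol for 24 h. There were no further arrays, so each group held 1 sample, and no p-value, standard deviation or standard error between cultures could be had.

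The deposited values were linear signal intensities, 1 per probe set, for 45101 probe sets on each array. Per the submitters' processing notes they came from Affymetrix GCOS, whose version is not given in the sources used here. The 2% trimmed mean over all probe sets was 500.0 in both arrays, which is how scaling to a common target leaves such values. Detection calls and probe-level files were not used here. Genes were named through the platform annotation supplied with the table: 34945 of the 45037 probe sets that were not array controls had 1 gene symbol, 932 had several and 9160 had none. Of the former, 34741 had an Entrez identifier in the RefSeq gene table for GRCm38.p6, which changed no symbol. Some listed genes had no probe set assigned to them alone and were not analysed here.

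The signals were rescaled so that both arrays shared 1 trimmed mean over the probe sets that were not controls. This left the values almost as deposited, with factors of 0.999941 and 1.00006. A floor was set at the 50th percentile of these signals over both arrays, a signal of 95.2. A probe set at or above the floor on both arrays was called measured, and its value is the log2 ratio of estradiol over untreated. Where only 1 array reached the floor, the other was raised to the floor and the ratio is a lower bound. No ratio was formed where both lay below it. A gene took the values of its brightest probe set, by mean signal, among those assigned to it alone. A gene was counted as higher or lower at 2-fold. The precision of a ratio is limited by the number of arrays. The error used for genes was the pooled SD of log2 ratios between probe sets of the same gene, 0.25 over 12514 probe sets of 4586 genes. It was 0.30, 0.25 and 0.20 in the lowest, middle and highest tertile of genes by signal. It covers probe noise and differences between transcript forms, not differences between cultures.

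The 25 gene lists, the rule for named genes, the floor, the thresholds and the alternatives were all fixed before the data were examined. Named genes are the 15 with the largest ratio in each direction, list members past 2-fold, the 5 brightest per direction among genes with a bound of at least 4-fold, and a short preset set that includes the GATA factors, globin genes, Lyl1, Rgs18, Kit, Myb, Myc, Alas2, Klf1 and Slc4a1. Further list members are given as examples by size of ratio. The median log2 ratio of a list was set against the medians of 10000 random lists of the same size, drawn from measured genes in the same of 20 bins of mean signal. Its percentile describes these 2 arrays and is not a test of the treatment. Lists with fewer than 3 measured members were given no percentile. Alternatives covered the scaling (signals as deposited, a common median, quantile normalization, loess with a span of 0.3), the floor (30th or 70th percentile, or none with 16 added to each signal), the probe set taken for a gene, and thresholds of 1.5-fold and 3-fold.

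The steps were tested on simulated data: 2 arrays drawn from the real signals with Gaussian noise of the size above and 200 changed genes. The changed genes were drawn from measured genes whose mean signal was at least 2-fold the floor, so recovery of dimmer genes was not tested. At true changes of 3-fold, 4-fold and 6-fold the 2-fold rule recovered 50 of 50, 50 of 50 and 42 of 42 measured genes. At 1.5-fold it called 2 of 50. It called 0 of 10385 unchanged genes, an outcome that holds for Gaussian noise only. Of 40 simulated lists of 12 genes raised by 0.5 on the log2 scale, 40 lay above the central 95% of random lists, and 1 of 40 unchanged lists lay outside it. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.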

Results

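Transcript levels were compared between G1E cells carrying ER-GATA-1(V205G) before treatment and the same cells after 24 h with 1 µM estradiol, which activates the fusion protein. Genes that differ are candidates for a response to a GATA-1 mutant defective in FOG-1 binding. The samples held no untreated array at 24 h and no array of cells without the fusion. Effects of the activated mutant, of estradiol itself and of 24 h in culture therefore cannot be told apart for any gene. Each condition was represented by 1 array. Of 45037 probe sets, 22139 (49.2%) were at or above the floor in untreated cells and 22904 (50.9%) after estradiol. Signals ran from 0.1 to 18099.6 and from 0.1 to 17883.8. Every difference below is between 2 arrays and has no replicate check. The size against which it can be read is the SD between probe sets of 1 gene, 0.25 on the log2 scale, of which 2 SD correspond to 1.42-fold.

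Most transcripts differed little, and more of those that differed were higher after estradiol. Of 10240 genes measured on both arrays, 209 were at least 2-fold higher after estradiol and 113 at least 2-fold lower, while 9015 (88.0%) lay within 1.5-fold. The median log2 ratio of all measured genes was 0.00. A further 40 genes rested below the floor without estradiol and were at least 2-fold above it with estradiol, and 34 showed the opposite. Among probe sets, 427 were at least 2-fold higher and 213 lower of 21054 measured. Of the 85 higher genes with several measured probe sets, 80 had all of them in the same direction and 42 had all of them past 2-fold. The numbers were 39 and 21 for the 47 lower genes of that kind. The counts depend on the floor: with the 70th percentile 130 genes were higher and 65 lower, and with no floor 679 and 512.

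**Figure D1:**
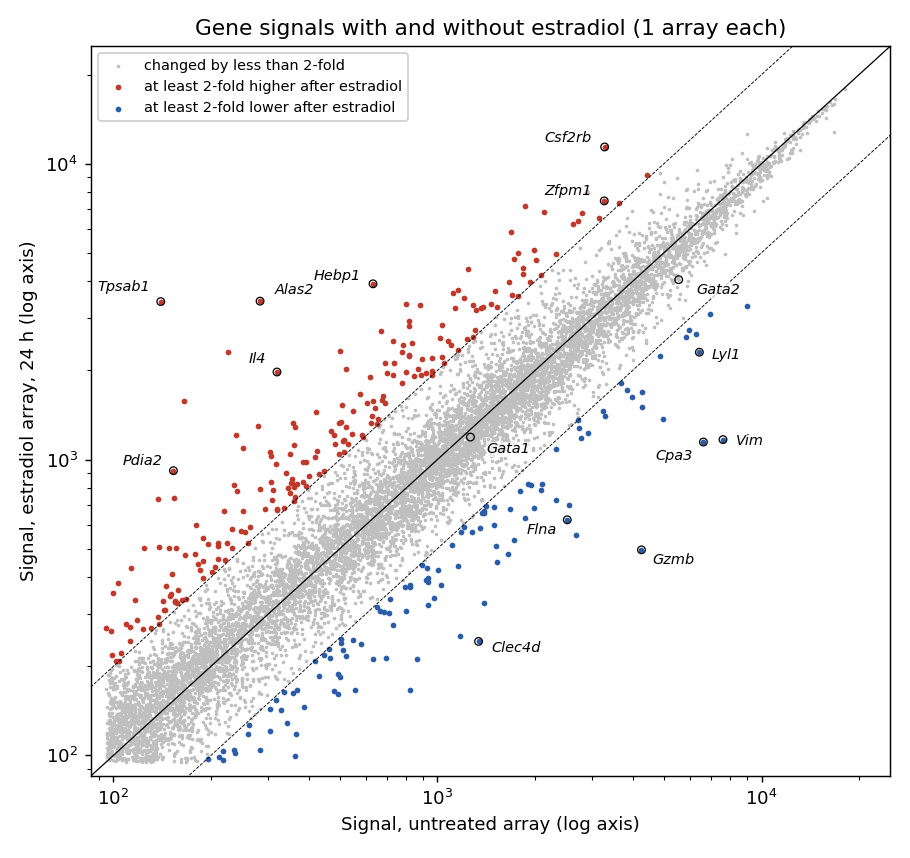
Signal of each gene measured on both arrays, untreated on the horizontal and estradiol on the vertical log axis, with 1 point per gene, a solid line of equality and dashed lines at 2-fold. The 209 genes at least 2-fold higher are red and the 113 lower are blue, with Tpsab1 and Alas2 farthest above the line and Gzmb, Vim and Cpa3 farthest below it.

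Among the GATA factors and their cofactors, Zfpm1 differed most. Zfpm1, which encodes FOG-1 itself, had a signal of 3271 untreated and 7485 with estradiol (2.29-fold higher, log2 ratio 1.19), and its other probe set had a log2 ratio of 1.66. The Gata1 probe set read 1264 and 1191, a log2 ratio of -0.09. Whether this probe set reads the fusion transcript is not known here, so it does not check the labels. Gata2, which encodes the GATA factor of early progenitors, read 5551 and 4054 (log2 ratio -0.45) with -0.56 on its other probe set. Both lie beyond 2 SD (0.40) between probe sets of genes in the highest tertile of signal. Gata3 stayed low at 195 and 223, and both probe sets of Zfpm2, the FOG-2 gene, were below the floor.

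The largest ratios upward were those of Tpsab1 and Alas2. Tpsab1, a mast cell tryptase, was 24.4-fold higher (signal 140 to 3418). Alas2, the erythroid form of the first enzyme of heme synthesis, was 12.1-fold higher (283 to 3430). Hebp1, which encodes a heme-binding protein, was 6.21-fold higher, and the cytokine gene Il4 was 6.18-fold higher. The chloride channel gene Ano1 was 5.32-fold higher, Lgmn, a lysosomal protease gene, 4.84-fold, and the nuclear receptor gene Ppard 4.65-fold. Cox7a1, a cytochrome c oxidase subunit gene, was 4.63-fold higher. 1700001L05Rik, Nxpe2, Pdia2 and Fam234a were 10.2-fold, 9.55-fold, 5.98-fold and 5.08-fold higher. The stress-response factor Ddit3 was 4.20-fold higher, with log2 ratios from 0.85 to 2.07 over its probe sets. Bach1, a repressor that binds heme, was 4.08-fold higher. Several of these genes were dim without estradiol, so their ratios depend on the floor. With a floor at the 70th percentile Tpsab1 had only a bound, a log2 ratio of 3.42. Nxpe2, Pdia2, Ano1 and Lgmn had bounds of 2.31, 1.52, 1.20 and 1.22, all still past 2-fold.

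The largest ratios downward were those of Gzmb, Vim and Cpa3. Gzmb, the granzyme B gene, was 8.60-fold lower (4260 to 495), Vim, the gene of the intermediate filament protein vimentin, 6.51-fold lower (7603 to 1168), and Cpa3, mast cell carboxypeptidase, 5.77-fold lower (6616 to 1146). The 3 probe sets of Vim ranged from -2.70 to -2.01 on the log2 scale. The lectin gene Clec4d was 5.51-fold lower and the sialyltransferase gene St8sia4 4.81-fold lower, a log2 ratio of -2.27 against -1.19 on its other probe set. Cyp11a1, the cholesterol side-chain cleavage enzyme, was 4.25-fold lower. The actin-binding protein genes Flna (filamin A) and Coro2a were 4.02-fold and 3.63-fold lower. The fucosyltransferase gene Fut8, the homeobox gene Hoxc8 and the sulfate-donor synthase gene Papss2 were 3.62-fold, 3.43-fold and 3.39-fold lower. Tmem44, Plp2 and Slitrk5 were 4.95-fold, 4.65-fold and 4.10-fold lower, with -2.31 and -1.52 on the log2 scale for the measured probe sets of Tmem44. Smim5 read 364 and 99.8, close to the floor, and a floor at the 70th percentile left a bound of -0.19.

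Some genes reached the floor on 1 array only. Ehf, an ETS-family factor gene, was at least 11.2-fold higher after estradiol, Cfap61 at least 9.22-fold, Mboat2 at least 7.26-fold, Dmtn at least 6.54-fold and Hbb-bh1 at least 6.19-fold. The measured other probe sets of Cfap61 and Dmtn had log2 ratios of 0.16 each, so the probe sets of these genes disagree. With a floor at the 70th percentile the bounds of Ehf, Mboat2 and Hbb-bh1 shrink to log2 ratios of 1.74, 1.12 and 0.89, the last short of 2-fold. Tespa1, G6pc3 and Sgsm2 were at least 4.95-fold, 4.40-fold and 4.14-fold lower, bounds that shrink to log2 ratios of -0.56, -0.39 and -0.31 with a floor at the 70th percentile. A Tespa1 probe set measured on both arrays had a log2 ratio of -1.99 (391 to 98.2).

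**Figure D2:**
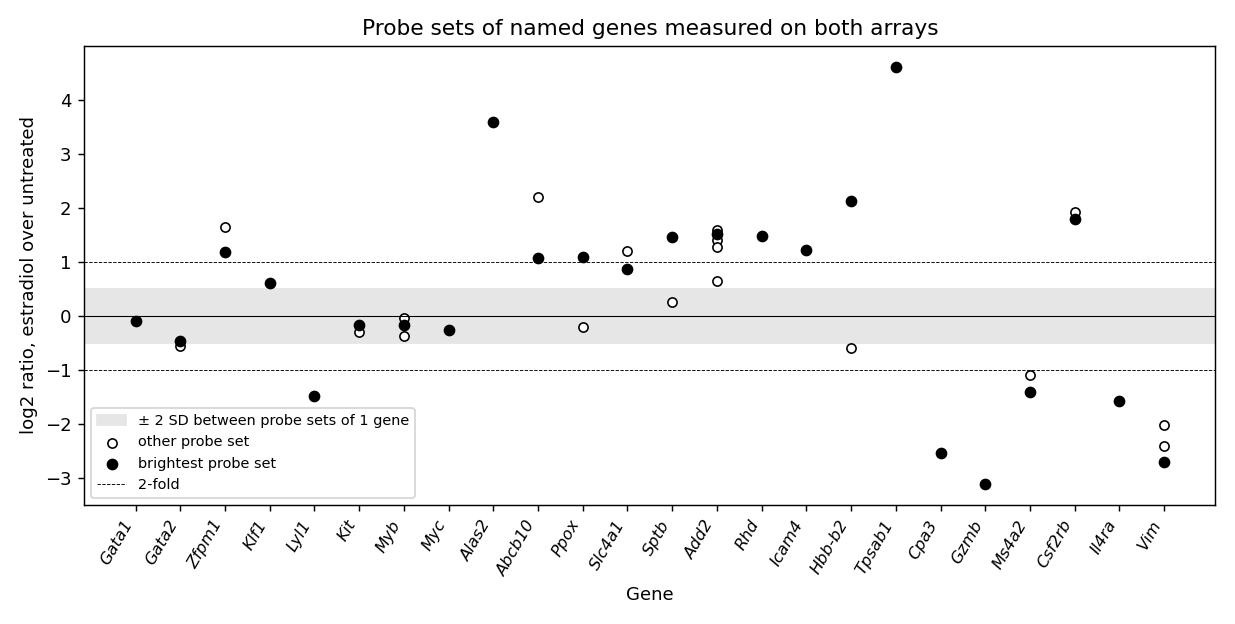
Log2 ratio of estradiol over untreated signal for the measured probe sets of 24 named genes. Filled points are the brightest probe set, open points the others, the grey band is 2 SD (0.50) between probe sets of 1 gene, and Hbb-b2 is the gene whose 2 probe sets lie farthest apart, at 2.12 and -0.58.

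Heme synthesis genes were higher as a group. Of 11 measured genes, 3 were at least 2-fold higher and none at least 2-fold lower. Beside Alas2 these were Ppox, a late enzyme of the pathway (2.14-fold), and Abcb10, a mitochondrial transporter (2.10-fold). The second Ppox probe set had a log2 ratio of -0.19, and that of Abcb10 was 2.20 against 1.07 for the brightest. Tmem14c (log2 ratio 0.93) and Slc25a38 (0.78) came next, and Fech, which inserts iron into the ring, read 7364 and 6596 (-0.16). The list median was 0.31, at the 99.96th percentile of matched random lists. Among 12 iron-handling genes none passed 2-fold. Slc25a37, the mitochondrial iron importer gene, had a log2 ratio of 0.67 and Steap3 0.63, and Tfr2 -0.97. Their median of 0.07 was at the 93.8th percentile.

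Red cell membrane and blood group genes had the highest list median. Of 14 measured genes 4 were at least 2-fold higher and none lower: Add2 (adducin) 2.87-fold, Rhd 2.79-fold, Sptb (erythroid beta spectrin) 2.76-fold and Icam4 2.34-fold. The other Sptb probe set had a log2 ratio of 0.26, and the lowest of 5 for Add2 was 0.65. Kel had a log2 ratio of 0.95, and Slc4a1, the band 3 anion exchanger gene, 0.86 with 1.21 on another probe set. The list median was 0.64, above the medians of all 10000 random lists. Among globin genes, Hbb-bh1, an embryonic beta-like gene, went from 26.7, below the floor, to 589, and its other probe sets from 6.50 to 507 and from 4.40 to 420. The Hbb-b2 probe set read 251 and 1093 (4.35-fold), but its second probe set had a log2 ratio of -0.58, and globin genes are close copies whose probes can cross-hybridise. Hba-a1 read 97.3 and 136, close to the floor, and Hba-a2, Hba-x and Hbb-y were below it on both arrays. Hbb-b1, Hbb-bs, Hbb-bt and Ahsp had no probe set assigned to them alone. Probe sets with several gene symbols were left out, and these could include ones shared by globin genes. The low signals therefore do not show that adult globin transcripts were scarce.

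Erythroid transcription factor genes went both ways. All 22 were measured: Bach1, Zfpm1 and Mafk (2.25-fold) were at least 2-fold higher, and Stat5a (2.37-fold) and Tcf3 (2.03-fold), which encodes an E protein, were at least 2-fold lower. The other Tcf3 probe sets had log2 ratios of -0.60 and -0.92, short of 2-fold, and after loess the brightest had -0.98. Klf1, a factor that activates beta-globin, read 4554 and 6997 (log2 ratio 0.62), Lmo2 had 0.70 and Tal1 -0.56. The list median of 0.28 was at the 99.98th percentile.

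Progenitor genes were lower by a small margin, with Lyl1 the exception in size. Lyl1, a basic helix-loop-helix factor gene, was 2.79-fold lower (6429 to 2305), the only 1 of 16 measured members past 2-fold. Flt3, a receptor gene of early progenitors, had a log2 ratio of -0.99. Kit (-0.16), Myb (-0.17) and Myc (-0.26) lay within the limit of 0.40 for the highest tertile of signal. Rgs18, a regulator of G-protein signalling, read 136 untreated and 17.5 with estradiol, which is below the floor and gives a bound of at least 1.42-fold lower. Id1 (0.89) and Hhex (0.69) lay above 0. The list median was -0.17, at the 1.70th percentile, and -0.19 with Rgs18 and Erg counted at their bounds.

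Mast cell genes moved in opposite directions. Of 7 measured members of the mast cell and basophil list, Tpsab1 was higher and Gzmb, Cpa3 and Ms4a2 (2.65-fold), the IgE receptor beta chain gene, were lower by at least 2-fold. The list median of 0.04 was at the 60.3rd percentile and the mean was -0.24. The median depended on the floor: it was -2.53 over the 3 members left at the 70th percentile, 0.35 over 12 members (98.7th percentile) at the 30th, and 0.18 with no floor. Hdc, the histamine-forming enzyme gene, and Slc18a2, a monoamine transporter gene, were below the floor untreated (3.80 and 81.9) and read 152 and 176 with estradiol. Fcer1a went the other way, from 144 to 47.3, below the floor, a bound of -0.60 on the log2 scale. Markers of other lineages were mostly near or below the floor. In the megakaryocyte and platelet list 9 members were measured, of which Plek was 2.02-fold lower and the others were within 2-fold, with Itga2b at 498 and 553 and a list median of 0.15 at the 69.4th percentile. Plek stayed past 2-fold under 7 of 9 alternatives, with log2 ratios from -1.28 to -0.54. Of the neutrophil and monocyte genes 4 were measured (median 0.14, 67.1st percentile), of the lymphoid genes 3 (median 0.18, 67.8th percentile), and of the 6 eosinophil genes on the array 0.

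**Figure D3:**
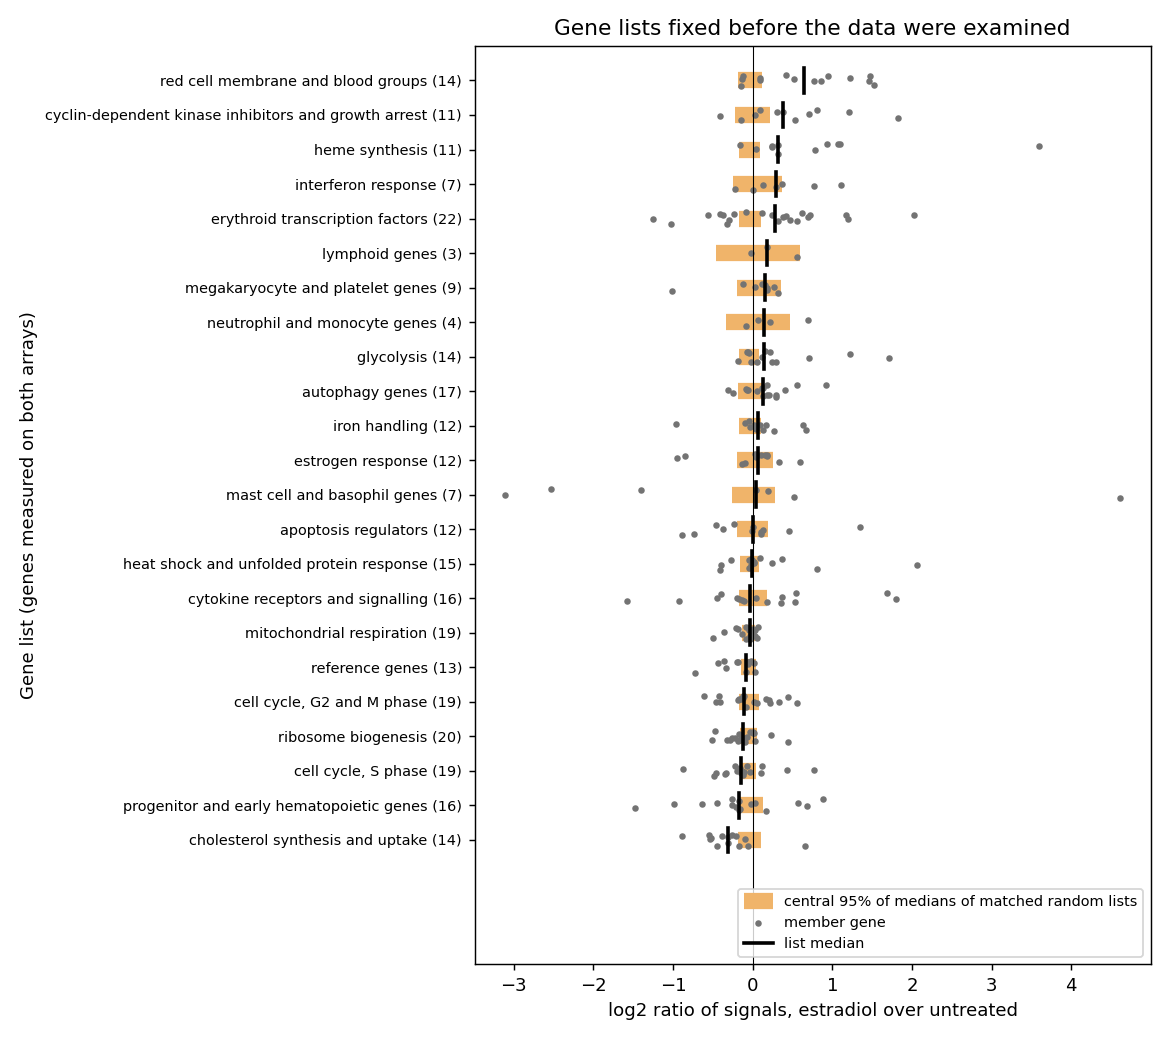
Log2 ratios of estradiol over untreated signal for the measured members (grey points) of 23 gene lists, with each list's median (black bar) and the central 95% of medians of matched random lists (orange). The medians of red cell membrane, heme synthesis, erythroid transcription factor, growth arrest and glycolysis genes lie above the orange range, and those of cholesterol synthesis, progenitor and S phase genes below it.

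Growth arrest genes were higher while cell cycle genes differed little. Of 11 measured kinase inhibitor and growth arrest genes, Btg2 was 3.55-fold higher and Gadd45a 2.32-fold higher, Cdkn1b (p27) had a log2 ratio of 0.81, and the list median of 0.38 was at the 99.8th percentile. None of 19 S phase genes or 19 G2 and M phase genes passed 2-fold. The S phase median was -0.15 (1.18th percentile), with Tk1, thymidine kinase, at -0.88 and Ccne1 at 0.77. It lay inside the central range under quantile normalization, with no floor and with the median over probe sets. The G2 and M phase median was -0.10 (14.9th percentile). Among 12 apoptosis genes Bnip3 was 2.55-fold higher, Bbc3 had a log2 ratio of -0.88 and Bid -0.74 (from -1.07 to -0.10 over its probe sets), and the list median was 0.00 (56.9th percentile) with a mean of -0.05. None of 17 autophagy genes passed 2-fold, Map1lc3a being highest at 0.92, and their median of 0.13 was at the 96.8th percentile.

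Cytokine receptor genes differed singly rather than as a list. Csf2rb, the common beta chain of the IL-3, IL-5 and GM-CSF receptors, was 3.47-fold higher (3280 to 11388) and its close relative Csf2rb2 3.21-fold higher (2133 to 6855), although probes for this pair can read both. Il4ra was 2.98-fold lower. Epor, the erythropoietin receptor gene, read 2516 and 2295 (-0.13). The list of 16 measured genes had a median of -0.04 (35.5th percentile) and a mean of 0.10.

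The list medians of glycolysis and cholesterol synthesis genes lay on opposite sides of the random range. Of 14 glycolysis genes Pfkm, a phosphofructokinase gene, was 3.27-fold higher and Hk2, a hexokinase gene, 2.34-fold higher, with Slc2a1 at 0.71. The list median of 0.14 was small though at the 99.6th percentile, with 9 members above 0 and 5 below. Bright members differed little, with Aldoa at 0.12, Ldha at 0.06, Pgk1 at -0.05, Tpi1 at -0.06 and Pkm at -0.19. Cholesterol synthesis genes were lower in 13 of 14 measured members, none past 2-fold: Dhcr7 had a log2 ratio of -0.89, Cyp51 -0.54, Fdft1 -0.53 (up to 0.09 on its other probe sets) and Hmgcs1 -0.52, and Pmvk was the exception at 0.65. Their median of -0.31 was at the 0.07th percentile. None of 20 ribosome biogenesis genes (median -0.13, 7.08th percentile) or 19 respiration genes (median -0.04, 61.3rd percentile) passed 2-fold.

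Genes of other responses mostly differed little. None of 12 measured estrogen response genes passed 2-fold, with Rara at -0.94, Pgr at 0.59, and Nrip1 at -0.85 on its brightest probe set but from -0.91 to 0.99 over 6, a median of 0.07 (65.7th percentile) and a mean of -0.04. Ddit3 was the only 1 of 15 heat shock and unfolded protein response genes past 2-fold, with Trib3 at 0.81, Hspa5 at -0.01, a list median of -0.01 (69.8th percentile) and a mean of 0.16. Usp18 was 2.16-fold higher among 7 interferon response genes (median 0.30, 93.4th percentile). None of 13 reference genes passed 2-fold (median -0.09, 21.2nd percentile), with Actb at 0.03 and Gusb at -0.73. Of the 23 lists with a median, 5 lay above and 3 below the central 95% of random lists. By construction 1.15 would fall outside if the members of a list varied independently. Genes of a pathway can move together between any 2 cultures, so the larger number is not a test of the treatment.

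The 3' to 5' ratios and the hybridisation controls were similar on both arrays, while some other control probe sets differed. The ratio of 3' to 5' signal was 1.14 untreated and 1.16 with estradiol for beta-actin, 0.798 and 0.781 for Gapdh, and 2.28 and 2.04 for the transferrin receptor. The 18 bacterial and phage hybridisation control probe sets, all measured, had a mean log2 ratio of 0.01 ± 0.13 (SD across probe sets), ranging from -0.17 to 0.25. The 3 probe sets for 18S ribosomal RNA were lower after estradiol, with log2 ratios of -0.20, -0.23 and -0.26, and the B1 repeat control was higher by 0.66.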

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

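All tests in this part were chosen after the results were seen. Signals outside the gene comparisons were noted where the estradiol array exceeded the untreated array by more than 2 SD of same-gene probe sets. The control probe set for B1 repeats (AFFX-MURINE_b1_at), a family of short interspersed elements, was higher by 0.66 on the log2 scale, from 2715 to 4276, and the B2 repeat controls were AFFX-MUR_b2_at at 1153 and 1485 (0.36) and the very bright AFFX-MURINE_B2_at at 13727 and 13909 (0.02). A pyruvate carboxylase control, the 3' probe set, was higher by 1.21, from 123 to 286, its 5' probe set by 0.43 and 1 middle probe set by 0.35, and the other middle probe set went from 23.8, below the floor, to 155. The 5' and middle controls for the transferrin receptor were higher by 0.56 and 0.58, and its 3' control by 0.40, and the 3 gene probe sets of Tfrc were higher by 0.13 to 0.51. Among the probe sets that could not be assigned to 1 gene, 51 of 2868 measured were at least 2-fold higher and 16 at least 2-fold lower. Together these are 2.34% of that class, against 3.04% of all 21054 measured probe sets. This class therefore did not differ more often than probe sets in general.

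Mast cell genes moved in both directions, with Tpsab1 higher and Gzmb, Cpa3 and Ms4a2 lower. A different share of mast cells or basophils in the treated culture would move these genes one way. Of the other members measured on both arrays the highest, Mcpt2, was at 0.52, within 2 SD (0.60) for genes of its signal. Cma1 and Fcer1g, also dim, were at 0.19 and 0.04, so the measured members other than Tpsab1 were not all lower. Slc18a2 and Hdc were higher by bounds of 0.88 and 0.67 but ended near the floor, at 176 and 152. Fcer1a was lower, with a bound of -0.60 from a dim signal of 144. The upward direction beyond Tpsab1 thus rests on dim genes. Tpsab1 itself goes against a changed share but is read by 1 probe set, so a changed share stays open. The number of Tpsab1 probe sets is 1, so cross-hybridisation to a related transcript is also open. The related tryptase gene Tpsb2 read only 47.1 and 100, near the floor, so its own signal does not point to it as the source. An effect of the activated GATA-1 mutant cannot be tested with 1 array per condition.

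Cholesterol synthesis genes lay below the other genes. A trend of the ratio with signal strength would also move random lists matched for signal. The list median of -0.31, at their 0.07th percentile, argues against it. After loess the median was -0.29, at the 0.02nd percentile. That is not a separate check, because the lists were already matched for signal. The list does not rest on its lowest members alone, since 13 of 14 measured members were below 0. Without Dhcr7 and Cyp51 the median was -0.28 and its percentile 0.14. That is a weak check, because a median moves little when 2 members are left out. With 1 pair of cultures measured, a difference in growth conditions between the flasks and an effect of the activated mutant cannot be told apart.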

How the results depend on the processing

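With 1 array per condition no array could be left out and other splits of the samples do not exist. No paired analysis was possible because each condition has 1 sample. Using the signals as deposited changed no count. Under common-median, quantile and loess scaling the higher genes numbered 193, 194 and 199 and the lower genes 125, 125 and 122, and the share of higher among changed genes was 60.7%, 60.8% and 62.0% against 64.9%. The counts moved with the floor and threshold: higher and lower genes numbered 439 and 288 at the 30th percentile, 130 and 65 at the 70th, 679 and 512 with no floor, 728 and 497 at 1.5-fold and 49 and 21 at 3-fold. At the 70th percentile fewer genes were measured, 7122 against 10240. Of 60 named genes past 2-fold, 59 kept their direction and 47 stayed past 2-fold under every alternative that measured them. The exception in direction was Hbb-b2, at -0.58 without probe sets ending in _x_at or _s_at, which leaves its other probe set. The kept directions say little, because a change of floor cannot reverse a ratio and rescaling shifted ratios only slightly. Only the choice of probe set could readily reverse 1, and genes with 1 probe set give that choice nothing to change. List medians moved by more than the spread in 11 of 202 repeats. No list outside the central 95% of random lists changed sign, whereas the medians near 0 of mast cell, apoptosis, cytokine receptor, respiration and heat shock genes did under some settings. With the median over probe sets, heme synthesis had 0.43, red cell membrane 0.52 and cytokine receptors 0.045. With the floor at the 30th percentile, red cell membrane had 0.47, mast cell genes 0.35 (98.7th percentile) and neutrophil and monocyte genes 0.45 (98.4th percentile). With the floor at the 70th, mast cell genes had -2.53 and apoptosis genes -0.11. With no floor, red cell membrane had 0.41, mast cell genes 0.18 and interferon response 0.089. The cause of these shifts was not tested. Signal near the floor limits the globin, megakaryocyte, myeloid and lymphoid genes, and for the brightest transcripts saturation was not examined.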

Other observations

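The tests in this part were all chosen after the values were seen. Genes higher after estradiol included several neighbours in the genome. With the 10226 measured genes placed in the order of the GRCm38.p6 gene table, the densest stretch of 10 consecutive measured genes held 5 at least 2-fold higher genes, in the order Decr2 (log2 ratio 1.31), Nme4 (1.28), Pdia2 (2.58), Fam234a (2.34) and Dusp1 (1.42). Between them lay Pgap6 (-0.14), Mrpl28 (0.17), Axin1 (-0.13), Rgs11 (0.53) and Luc7l (0.24). In the mouse gene table this stretch lies on chromosome 17, and the measured alpha-globin gene Hba-a1 is not among its 10 genes. In humans the counterparts of several of these genes flank the alpha-globin cluster, which does not place the mouse stretch beside alpha-globin genes. Other adjacent pairs that were both at least 2-fold higher included Ddc and 1700042O10Rik, Ache and Ufsp1, Ppard and Fance, and Mospd1 and Ints6l.

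In 10000 random orders of the genes, the densest stretch held a median of 3 such genes and the central 95% ended at 4. Only 0.42% of orders reached 5, so the count is rare, but chance placement stays open. The length of the stretch was chosen after the values were seen, and only 1 stretch reached 5, with Dusp1 at its end. Decr2, Pdia2, Fam234a and Dusp1 were dim untreated (210, 153, 238 and 179), and the count was not repeated with another floor. Adjacent pairs in general were another matter: 9 pairs were observed where the central 95% of random orders ended at 8, but only 7 once pairs with symbols of the same stem, such as Csf2rb with Csf2rb2 and Tubb2a with Tubb2b, were left out. That is within the random range, so related probe sequences remain a candidate explanation for the excess of pairs. A shared regulatory element at the Decr2 to Dusp1 stretch may be a hypothesis for follow-up, and these arrays hold no test of it. Among lower genes the densest stretch held 3, as in 35.8% of random orders.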
